A study of Mus musculus with 2 samples.

How the data were processed

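Small RNA of mouse spinal cord was measured on spotted microarrays at 2 stages, embryonic day 13.5 (E13.5) and birth (postnatal day 0, P0). Per the labels' protocols, total RNA was extracted with Trizol, the small RNA fraction was cut from a gel, adapters were ligated to it, and the cDNA was amplified by PCR with a Cy5 primer before hybridisation to oligonucleotide probes against miRNAs. Per the labels, each stage is 1 pool of 3 biological replications, and each pool was run on 2 technical arrays. At which step the technical replication began is not given in the sources used here.

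The deposited scanner values are Cy5 intensity per spot on a linear 16-bit scale, which ends at 65535. Per the file headers, they were quantified with a fixed circle method and were neither background subtracted nor corrected for crosstalk. The local background was above 0 in 0 to 25 spots of an array. Each of the 406 miRNA probes, numbered with the letter M, was printed in 3 adjacent spots. The arrays also carried 4 control names starting with B, 14 starting with N and 8 starting with P, and the files do not define these letters. The B spots had the lowest intensities as a group and were read as blanks, but some N names were dimmer than some B names. Mean intensities were 112 for B3 and 85 for N9 on E13.5 array 1, and 87 for B1 and 60 for N9 on P0 array 2. Per the file headers, the circle area was 6625 on E13.5 array 1, 5525 on E13.5 array 2 and 7700 on both P0 arrays, in the scanner's units.

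The authors' processed table holds 1 intensity per probe and stage, with no error. Its medians were 453 for E13.5 and 472 for P0. Across probes, the log2 values of each column correlated with the 2 arrays of its own stage at r = 0.990 to 0.997 and with those of the other stage at r = 0.918 to 0.928. A weighted sum of the 2 arrays accounted for 99.96% of the variance across probes in the E13.5 column and 99.99% in the P0 column, and the median ratio of the table to the mean of the 2 arrays was 1.05 for E13.5 and 0.958 for P0. The table is thus on a linear scale and runs in the same direction as the arrays. The rule by which its arrays were scaled is not given in the sources used here.

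From the scanner intensities, background was corrected with normexp and an offset of 50 on all spots (limma 3.58.1 in R 4.3.3). Control spots and the 2 spots marked as ignored in the files, both on E13.5 array 1, were then left out, the spots of a probe were averaged on the log2 scale, and the arrays were quantile normalized over all miRNA probes. A probe was above background on an array when over 50% of its spots exceeded the mean + 2 SD of the 12 blank spots of that array. Probes above background on both arrays of at least 1 stage were compared. A probe was called higher or lower when the stage means differed by at least 1 on the log2 scale and both arrays of 1 stage lay beyond both arrays of the other. For a probe above background at only 1 stage, brighter over dimmer is given as a lower bound, which depends on the scaling. No fold is given for a probe saturated on both arrays of a stage. For a dim stage the bound uses, per array, the higher of the probe's own normalized signal and the lowest signal among probes above background.

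No test of a difference between the stages was run for any probe and no p-value is given, because each stage is 1 pooled sample. Random orders, random assignments to blocks and bootstrap intervals were drawn over probes, which are not replicates, and describe these arrays alone. SDs are between the 2 technical arrays of a pool and leave out the spread between animals, and the number of arrays limits the precision. On simulated arrays for the comparison of P0 with E13.5, levels came from the 406 probes and the technical SD from the compared probes. The rule found 17 of 20 probes changed 3-fold, 20 of 20 changed 4-fold and 20 of 20 changed 8-fold. It called 0 of 260 unchanged probes. The changed probes were drawn from those above background on all arrays, with equal numbers each way. Their median fitted log2 difference was 1.85 for 4-fold and 2.73 for 8-fold, below the true 2 and 3, so fitted sizes can fall short. Simulated noise was independent between probes, with 1 SD for both stages. The simulation thus says little about false calls from differences shared by a block or by neighbouring probes.

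The rule for named probes, the processing settings and most alternatives were fixed before the data were examined. The rule asked for the 12 largest differences each way among probes above background on all arrays, the largest bounds, members of miRNA lists and the 5 brightest miRNAs of each stage. The files do not pair probe numbers with miRNA names or species, so the lists, including markers of other cell types, were not applied, all miRNA probes took the place of the mouse probes, and only the 2 largest differences each way are named, by probe number. Alternatives covered the background correction, the normalization, the filter on dim probes, the averaging of spots, the size of difference, each array left out in turn and the authors' table. Centring each block of an array, the random assignment of probes to blocks, blank thresholds from the median and MAD or from blank and N spots together, cyclic loess for the technical SD, keeping the ignored spots and centring the authors' table were added after the data had been seen.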

Results

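The level of miRNAs, short RNAs that lower the translation and stability of the mRNAs they pair with, was measured in the spinal cord of C57BL/6 mice at embryonic day 13.5 and at birth. The data comprised 1 pooled sample per stage, each on 2 technical arrays, with 406 miRNA probes. The comparison addressed which miRNA probes differ between the embryonic and the newborn cord. The files do not pair the probe numbers with miRNA names, so probes are given by number and groups of probes by their level and difference. There were no biological replicates, and every difference below describes these 2 pools.

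The median probe intensity was 504 on E13.5 array 1, 389 on E13.5 array 2, 454 on P0 array 1 and 473 on P0 array 2, and the summed probe intensity over the 406 probes ranged from 1139300 to 1394000. Probes above background numbered 318 and 370 on the E13.5 arrays and 369 and 294 on the P0 arrays. At E13.5, 316 probes were above background on both arrays, at P0 294 were, and 286 were on all 4 arrays. Blank thresholds were 167 and 71 on the E13.5 arrays and 68 and 138 on the P0 arrays, and these counts follow them. With thresholds from the median and MAD of the blanks, the counts were 337 at E13.5, 342 at P0 and 324 on all 4 arrays. The order of the stages thus turned with the threshold. All these counts rest on reading only the B control spots as blanks. With the N control spots included, they were 103 at E13.5, 143 at P0 and 96 on all 4 arrays.

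Of the 324 probes compared, 41 were higher at P0 and 40 were lower, which together made up 25% of the probes. The median difference was 1.55 on the log2 scale among the higher probes, and the lower probes lay a median of 1.36 below their E13.5 level. A difference of at least 2 on the log2 scale was found for 8 higher and 10 lower probes, and of at least 3 for 2 higher and 2 lower probes. Over all 324 probes the median absolute difference was 0.56, and 50.9% of them differed by less than 0.58. The balance of the directions depended on the scaling. Scaling to the median of the probes above background on all arrays gave 56 higher and 30 lower probes. In the authors' deposited table, which has 1 value per stage and a median difference of -0.18 over the compared probes, 36 probes were higher and 60 lower by at least 2-fold. With the table centred on that median, 47 were higher and 47 lower. With blank and N control spots together as the threshold, 150 probes were compared, of which 30 were higher and 25 lower.

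**Figure D1:**
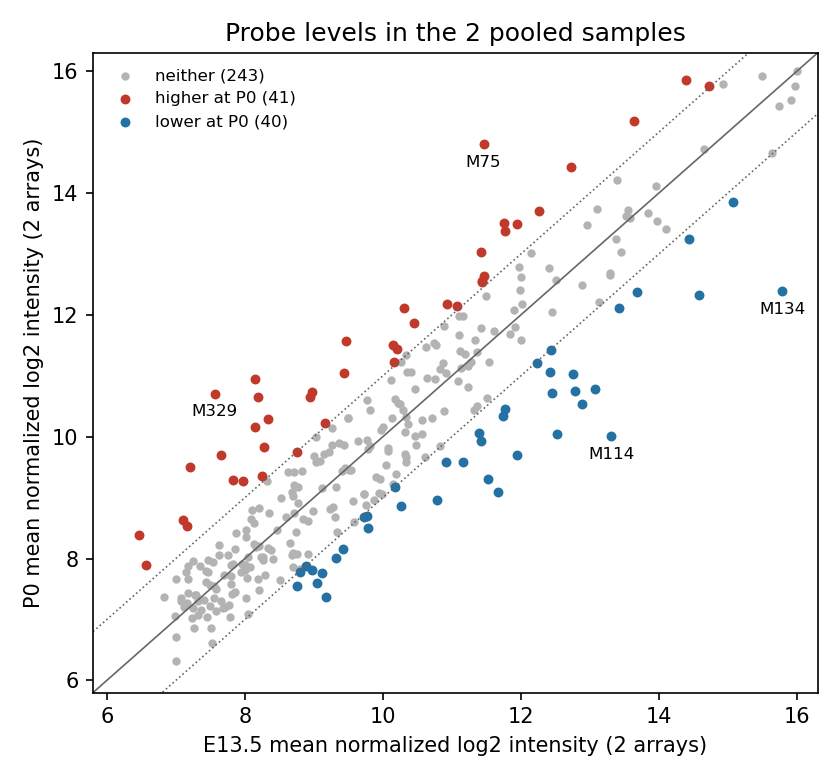
Mean normalized log2 intensity at P0 (y axis) against E13.5 (x axis), 1 point per probe for the 324 probes compared. The solid line marks equal levels and the dotted lines a difference of 1; 41 probes higher at P0 and 40 lower are coloured, and the 4 named probes lie farthest from the solid line among probes above background on all arrays.

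The largest increase among probes above background on all arrays was that of M75, whose normalized log2 intensity was 11.46 at E13.5 and 14.80 at P0, a difference of 3.34. Its rank was the same on both arrays of a stage, so quantile normalization left an SD of 0 there; its raw intensities were 3001 and 2694 at E13.5 and 23877 and 33188 at P0. M329 followed, with 7.56 ± 0.16 (technical SD, n = 2 arrays) at E13.5 and 10.71 ± 0.19 (n = 2 arrays) at P0, a difference of 3.15. The order of these 2 probes depended on the processing. M329 exceeded M75 with an offset of 16 (3.42 against 3.36) and with cyclic loess (3.09 against 3.03). M75 was larger in every other alternative. With the main settings, the largest decrease was that of M134, from 15.79 ± 0.10 (technical SD, n = 2 arrays) to 12.39 ± 0.02 (n = 2 arrays), a difference of -3.40. M114 went from 13.31 ± 0.45 (technical SD, n = 2 arrays) to 10.01 ± 0.12 (n = 2 arrays), a difference of -3.30. The order of M134 and M114 also depended on the processing. M114 fell further without normalization between arrays (-3.35 against -3.19) and without E13.5 array 1 (-3.73 against -3.47). It also did so with scaling to the median (-3.18 against -3.02) or the 75th percentile (-3.24 against -3.08), in the authors' table and after block centring. M134 fell further in the other alternatives. The technical SD pooled over the compared probes was 0.33. The named probes were picked as the largest among differences of at least 1, so lying beyond that SD is no further support. In the authors' deposited table these differences were 3.18, 2.97, -3.33 and -3.53. M75 and M329 lay in the same block of the array, whose probes had a median difference of 0.33. After each block was centred, their differences were 2.70 and 2.66, and those of M134 and M114 were -3.58 and -3.69.

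**Figure D2:**
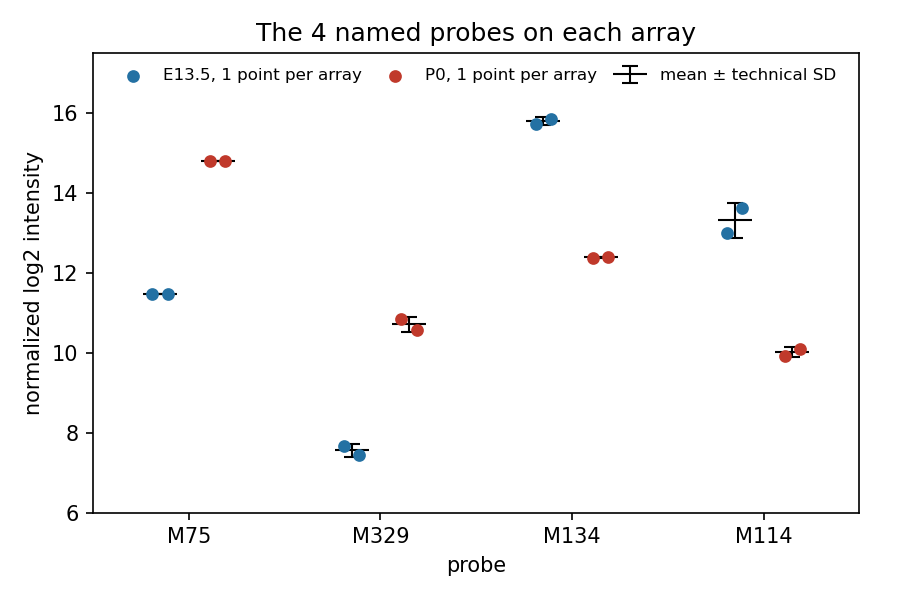
Normalized log2 intensity (y axis) of the 4 named probes on each array, with E13.5 in blue and P0 in red. Points are single arrays, and black bars give the mean and the technical SD of 2 arrays; for each probe both arrays of 1 stage lie above both of the other.

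Differences were found in each level group. When the compared probes were ranked by mean level into 4 groups of 81, the dimmest group held 4 higher and 1 lower probes, the next 12 and 12, the next 9 and 11, and the brightest 16 and 16. The median absolute difference was 0.33 in the dimmest group and 0.82 in the brightest. The offset of the background correction weighs most on dim probes and can shrink their log2 differences and calls. With a smaller offset of 16, 44 of the compared probes were called higher and 46 lower, against 41 and 40 with the main settings. These values thus do not tell whether bright probes differed more between the pools than dim ones.

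Few probes were above background at a single stage. On both P0 arrays and no E13.5 array there was 1 probe, at least 2.99-fold brighter at P0 after quantile normalization. On both E13.5 arrays and no P0 array there were 2, neither of which reached a bound of 2-fold; the larger was at least 1.55-fold. A further 28 probes were above background on both E13.5 arrays and 1 P0 array, and 7 on both P0 arrays and 1 E13.5 array. These counts also follow the blank threshold, which was higher on 1 array of each stage. On no array were 19 probes above background. Most spots of 1 probe were saturated on all 4 arrays, so no fold can be given for it. Another was saturated on both P0 arrays alone and 1 on both E13.5 arrays alone, and no fold is given for these either. Saturation on only 1 array of a stage was not counted. On P0 array 2, M2, which was called higher, had the same normalized value as M69, the probe saturated on all 4 arrays (15.99). Its difference of 1.46 may thus be too small.

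The differences between the 2 pools exceeded those between technical arrays. The SD of the log2 difference over the compared probes was 0.97 between stage means, 0.53 between the E13.5 arrays and 0.39 between the P0 arrays. A difference of at least 1 was found for 16 probes between the E13.5 arrays, for 4 between the P0 arrays and for 91 to 98 between single arrays of different stages. Across probes, which are not independent replicates, Pearson's r of log2 intensity was 0.970 for the E13.5 arrays, 0.983 for the P0 arrays and 0.881 to 0.894 for arrays of different stages. Both arrays of 1 stage lay beyond both of the other for 66.0% of the probes. Chance gives 33.3% if all 4 arrays are exchangeable, which technical arrays of different pools are not, so this share describes these pools and not the stages.

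**Figure D3:**
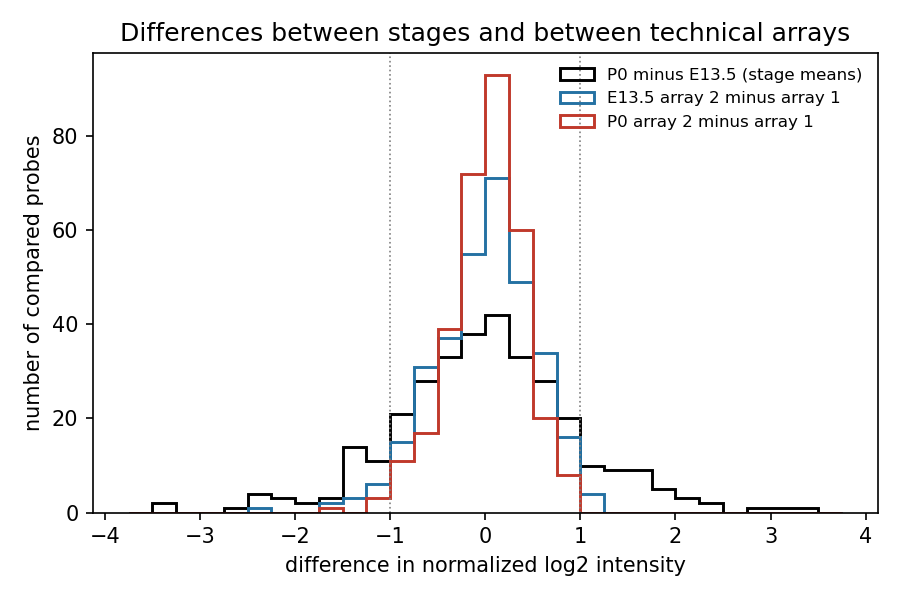
Number of compared probes (y axis) by difference in normalized log2 intensity (x axis), in bins of equal width. The black line gives P0 minus E13.5 stage means (SD 0.97), the blue line the E13.5 arrays (SD 0.53) and the red line the P0 arrays (SD 0.39); dotted lines mark differences of 1.

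Stage differences also varied with the block of the array in which a probe was printed, and the arrays differed in header and circle area. The probes of 1 of the 4 blocks had a median difference of 0.33 between the stages, with 17 higher and 5 lower probes among 79, and in 34 of 10000 random assignments of probes to blocks a block median was as far from 0. After the blocks were centred, 44 probes were higher and 40 lower, of which 32 and 31 were among the 41 and 40. The header of E13.5 array 1 differs from those of the other 3 arrays in its experiment label. Without that array 371 probes were compared, and without P0 array 2 also 371. With 1 array left at a stage, the filter and the separation of arrays ask less of that stage. The counts therefore cannot tell whether E13.5 array 1 has an effect of its own. No circle area for reading the spots was used at both stages, and the 2 areas within E13.5 go with the 2 arrays compared above. Circle area therefore cannot be told apart from the pool in any stage difference given here.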

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

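Control spots outside the comparison carried signal above the blanks. Of the 14 control names starting with N, 8 were above the blank threshold on all 4 arrays. The brightest, N2, had a mean intensity of 2108 on the E13.5 arrays and 1031 on the P0 arrays. Of the N names, 7 were lower on both P0 arrays than on both E13.5 arrays and 1 was higher on both. The files do not say what the N spots hold, and no explanation was tested.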

How the results depend on the processing

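Block centring, the blank thresholds from the median and MAD or from blank and N spots together, cyclic loess for the technical SD, the kept ignored spots and the centred table were chosen after seeing the data. Under every alternative run, no probe among the 81 called changed the sign of its difference. Leaving out 1 array at a time gave 40 to 51 higher and 42 to 52 lower probes. The other backgrounds, normalizations, filters, spot medians and the authors' deposited table gave 36 to 56 higher and 30 to 60 lower probes, except for the thresholds named next. A size of 0.58 gave 77 higher and 79 lower probes and a size of 2 gave 8 and 10, by construction. Blank and N control spots together as the threshold left 25 lower probes and 103, 143 and 96 probes above background at E13.5, at P0 and on all 4 arrays, since fewer probes passed. With the local background of the spot, which was 0 for nearly all spots, all 406 probes passed, so that setting sets no limit. The SD between technical arrays ranged from 0.44 to 0.55 for E13.5 and from 0.39 to 0.42 for P0. Of 19 alternatives for each named probe, 1 moved M75, 1 moved M329, 1 moved M134 and 2 moved M114. A move was a change by more than the pooled technical SD of 0.33. Ranges were 2.70 to 3.47, 2.66 to 3.42, -3.58 to -3.02 and -3.73 to -3.0. Alternatives that change only the filter on dim probes or the blank threshold cannot move a value, so fewer than 19 were informative. Without E13.5 array 1, M114 differed by -3.73. The list medians, the mouse probes alone and the guide strands alone were not run, because the files do not pair probes with names. No paired analysis was possible because each stage is 1 pooled sample. Signal over background limits the comparison: 82 of the 406 probes were not above background on both arrays of either stage and were left out.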

Other observations

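The tests on the spread of the E13.5 arrays and on the authors' table were chosen after the result was seen; those on neighbouring probe numbers were set before their values were computed, after the pattern had been noticed among the largest differences.

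Probes with neighbouring numbers differed between the stages alike: across 276 pairs of consecutive numbers, which are printed in different blocks, Spearman's rho of the stage differences was 0.257, which 0 of 10000 random orders reached. Pairs at a different position within the block had a rho of 0.218, where 341 of 10000 random orders were as high, and the rho of probes next to each other in 1 block minus that of consecutive numbers was -0.019 (bootstrap interval -0.184 to 0.148). For the difference between technical arrays, probes next to each other had a rho of 0.528 at E13.5 and 0.368 at P0, consecutive numbers -0.10 and 0.087, and consecutive numbers at the same position 0.079 and 0.196. Technical differences were thus shared by probes next to each other and little by consecutive numbers, but for the stage differences the interval above includes 0, so position and distance on the array stay open. That numbers follow related miRNAs may also account for the pattern, and it was not tested because the files do not pair numbers with names.

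The E13.5 arrays differed from each other more than the P0 arrays did, with a ratio of SDs of 1.34 (bootstrap interval over probes 1.18 to 1.51). A trend of the difference with signal level is argued against only weakly as the whole cause, since the ratio was 1.24 (1.09 to 1.4) after cyclic loess. The bootstrap treats probes as independent, but probes next to each other shared technical differences. The intervals for these ratios may thus be too narrow. Array position remains open: the block medians of array 2 minus array 1 ran from -0.49 to 0.25 at E13.5 and from -0.04 to 0.15 at P0, and after block centring the ratio was 1.08 (0.942 to 1.24). The circle area differed between the E13.5 arrays and not between the P0 arrays and was not tested. No biological explanation applies within a pool.

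The authors' deposited table held more lower than higher probes, 60 against 36, a share of 62.5% lower, where quantile normalization gave 49.4%. A single scale factor between the stages stays open for these counts: with the table centred on its median, 47 probes were higher and 47 lower (50% lower). Centring also sets the median difference to 0, so an even split decides little. The difference in the table minus the normalized difference did change with level. Its median was -0.35 among the 81 dimmest compared probes and -0.02 among the 81 brightest, 0.33 apart (bootstrap interval 0.27 to 0.39). Of the 20 probes lower in the table alone, 14 were in the dimmer 50% of probes. The normalized values carry an offset of 50 and quantile normalization, so this change may come from either side. A shift of the table that depends on the level also stays open. Without normalization, 40 probes were higher and 47 lower with all arrays (54.0% lower), 51 and 47 without E13.5 array 1 (48.0%), and 38 and 62 without E13.5 array 2 (62.0%). The share with all arrays was already within 10 percentage points of 49.4%, so these values decide nothing about a response particular to E13.5 array 1. A difference in total miRNA between the stages was not tested and cannot be read from scaled arrays.

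The 8 control names starting with P differed between the stages by -0.62 to 1.30 on the log2 scale before normalization, with a median of 0.25, and 5 of them were higher at P0. They also differed between the E13.5 arrays, in both directions. Mean intensities on E13.5 arrays 1 and 2 were 5310 and 2182 for P10E, 2072 and 920 for P5E, and 5917 and 7953 for P20S. The stage difference of a name can thus rest on a single array.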
